A study of Mus musculus with 56 samples.

How the data were processed

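RNA-seq libraries were made from multipotent progenitors (MPP) and granulocyte-macrophage progenitors (GMP) of WT and Tet2-/-Flt3ITD (T2F3) mice with a stranded mRNA kit, per the labels' protocols. The authors deposited 1 table of log2 expression values for 24424 genes named by Entrez ID in 15 libraries. Its name marks the values as regularized log values, and the submitters' processing notes name STAR, Bowtie, HOMER and DESeq2 and the mm9 build without versions, roles or settings. The regularized log shrinks the values of genes with few reads, so differences of low genes are understated, and the values hold no counts, so the depth of each library is unknown and no counting error is given. Values ran from -3.82 to 19.64, and 5135 genes were listed at exactly 0 in all libraries. Entrez IDs were matched to symbols with the NCBI gene table of the GRCm38.p6 assembly, and 24345 of 24424 matched. Since that assembly is not the submitters' build, no coordinates are given. The table's columns were mapped to samples by genotype, replicate number and population in their names. The 41 hydroxymethylcytosine and input samples of the 56 in the series were not analysed here.

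Genes with a mean of at least 4 over the 15 libraries were tested, 12133 in all. One limma model (version 3.58.1, R 4.3.3; lmFit, then eBayes with trend and robust) with a mean per group was fitted to all 15 libraries, and 5 contrasts were taken: T2F3 minus WT in MPP and in GMP, the difference of these effects (GMP minus MPP), and GMP minus MPP in WT and in T2F3. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05, without a minimum fold. Differences are on the log2 scale of the table with limma's SE, and levels are the group mean with the SD over libraries. Gene lists of blood lineages, signalling targets, surface markers and cell functions were tested with camera at a preset correlation of 0.01 between genes. Of the 31 lists with genes in the table, 30 were tested, since the sex-linked list had 4 tested genes and the smallest list allowed was 5. The list of mitochondrially encoded genes had no genes in the table. Of the list entries 4 found no match, all of them immunoglobulin constant genes. Camera, an estimated correlation and fry were run for each list and contrast, over 30 lists in each family.

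The contrasts, lists, filter and naming rule were set before the data were examined. Named genes were Tet2 and Flt3, the 8 largest rises and falls past the threshold whose groups of libraries did not overlap, and up to 14 list members with the smallest p, at most 2 per list. For the difference of effects, the 6 largest of each sign were taken. Predicted genes, pseudogenes and antigen receptor segments were not named, and some genes that the rule or the examples took are not reported here. Examples outside this rule are said to be chosen after their values were seen. Groups lay apart in 54.1% of tested genes in MPP and 17.0% in GMP, where chance alone gives 5.71% and 3.57%.

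The model was tested on simulated data for 12133 genes with 200 changed, 50 of each size. For the MPP contrast, 50% of changes of 0.5 log2, 86% of changes of 1 and 100% of changes of 2 were recovered, and for the GMP contrast 54%, 92% and 100%. For the difference of effects it was 16%, 76% and 98%, for the WT step 66%, 96% and 100%, and for the T2F3 step 48%, 90% and 100%. Between 2.87% and 5.46% of calls were false. The noise was drawn independently for each gene and library, so these shares do not cover genes that move together or libraries that stand apart. Alternatives were no filter, a minimum mean of 6, a pseudocount of 8, centring on the median, quantile normalization, no trend or robust step, array weights, the groups of a comparison alone, a test against a log2 difference of 0.5, the replicate number as a block, genotype and number as 1 animal, an estimated list correlation, fry and each library left out. After the data were seen, 3 more were added: leaving out WT GMP 1 and T2F3 GMP 2, the ribosomal protein score as a covariate, and a sex term. Table joins and figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.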

Results

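Gene expression was measured by RNA-seq in 2 progenitor populations sorted from the bone marrow of C57BL/6 mice. The mutant mice lacked Tet2, an enzyme that oxidizes 5-methylcytosine in DNA, and carried an internal tandem duplication in the receptor tyrosine kinase gene Flt3, and are called T2F3 here. Multipotent progenitors (MPP) were lineage-negative, Sca-1-positive and c-Kit-positive cells with CD48 and without CD150. Granulocyte-macrophage progenitors (GMP) were lineage-negative, Sca-1-negative and c-Kit-positive cells with CD34 and CD16/32. The table held 4 WT MPP, 3 T2F3 MPP, 5 WT GMP and 3 T2F3 GMP libraries. Values were log2 expression values for 24424 genes, of which 12133 were tested. The read depth of each library is unknown, because the values hold no counts. The 41 hydroxymethylcytosine and input samples of the series were not analysed here.

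The targeted genes were examined first. Tet2 was read at similar levels in both genotypes, at 9.79 ± 0.08 in WT MPP (SD, n = 4) and 9.75 ± 0.13 in T2F3 MPP (SD, n = 3). In GMP it stood at 10.06 ± 0.13 in WT (SD, n = 5) and 10.12 ± 0.21 in T2F3 (SD, n = 3). The difference, T2F3 minus WT, was -0.04 ± 0.11 (SE) in MPP, with a limma adjusted p of 0.783, and 0.06 ± 0.10 in GMP, with an adjusted p of 0.762. The GMP value changed sign without WT GMP 1 and T2F3 GMP 2 (-0.020) and under array weights (-0.11). A gene-level value does not check a deletion of part of a gene, so Tet2 neither matched nor contradicted the labels. Flt3, the receptor for FLT3 ligand, did not pass the threshold in MPP (-0.06 ± 0.12, adjusted p = 0.685). In GMP it was 2.43-fold higher in T2F3 (1.28 ± 0.11 on the log2 scale, SE, adjusted p = 8.23e-07), at 10.09 ± 0.33 (SD, n = 3) against 8.81 ± 0.07 in WT (SD, n = 5). The difference between the 2 effects was 1.34 ± 0.17 (SE, adjusted p = 4.66e-04).

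**Figure D1:**
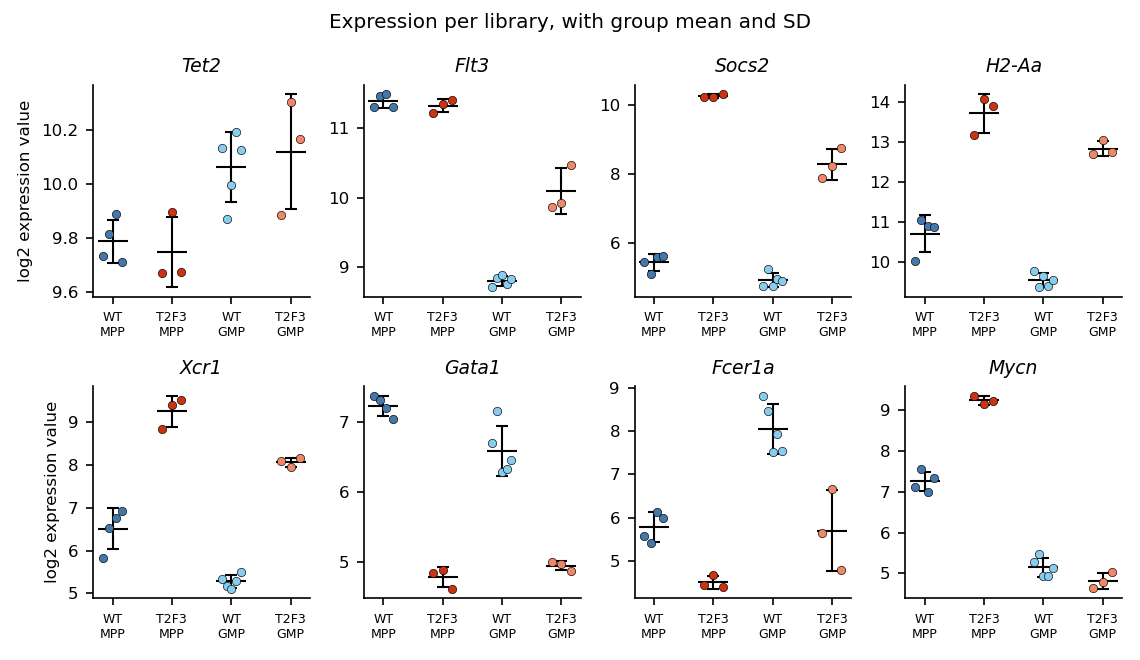
Log2 expression values (y axis) of 8 genes in each library of the 4 groups (x axis), where points are libraries and bars are the group mean and SD. Socs2, H2-Aa and Xcr1 are higher in T2F3 in both populations, Gata1 and Fcer1a are lower, Flt3 differs in GMP (log2 difference 1.28) and Mycn in MPP (2.00).

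The libraries separated by population on the first principal component, which held 46.1% of the variance, and by genotype on the second, with 32.0%. On the third, with 8.4%, WT GMP 1 (-34.0) and T2F3 GMP 2 (-17.0) lay at the low end and T2F3 GMP 3 (21.7) at the high end. In WT GMP 1 and T2F3 GMP 2 the ribosomal protein genes lay 1.08 and 0.81 above the mean of the other libraries of their group (log2, median over 76 genes). The oxidative phosphorylation genes lay 0.74 and 0.50 above it (median over 46 genes). T2F3 GMP 3 deviated the other way, at -0.63 and -0.49 for these lists. No 2 libraries were identical, and the lowest correlation across genes within a group was 0.973. Nothing in the labels names a separate animal for each library, so the p-values measure the spread between these libraries.

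**Figure D2:**
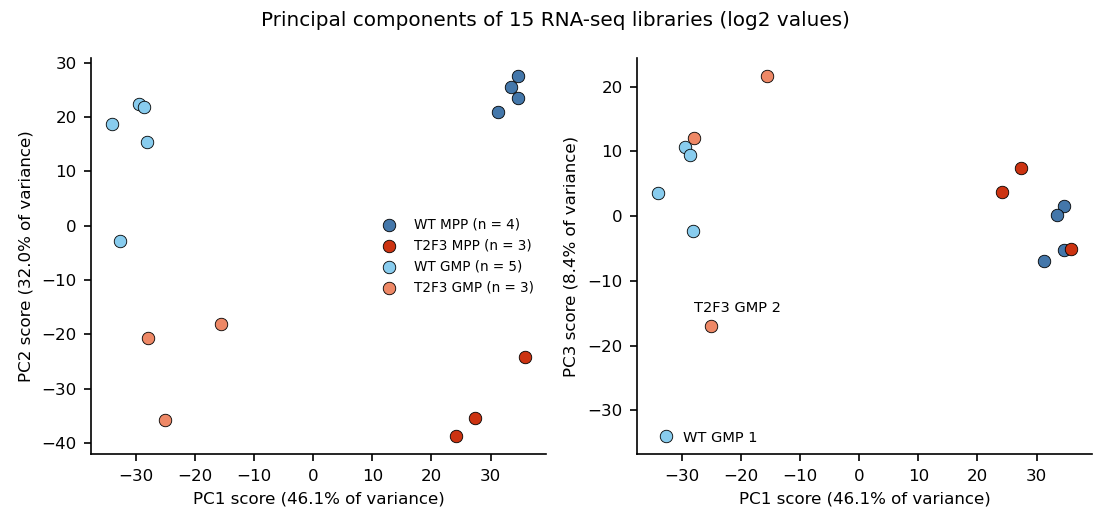
Principal component scores of the 15 libraries, with the first component on both x axes and the second and the third on the y axes, and the share of variance in brackets. Populations part on the first component (46.1%), genotypes on the second (32.0%), and WT GMP 1 and T2F3 GMP 2 lie at the low end of the right plot (8.4%).

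The first comparison asked how the T2F3 genotype changed expression in multipotent progenitors. By camera, the lists of cytokine feedback targets (7 of 12 genes rose) and of dendritic cell genes were higher in T2F3 MPP, and the erythroid and B lymphoid lists were lower. With an estimated correlation none of these lists passed, at adjusted p = 0.205, 0.287, 0.183 and 0.289 in that order. Socs2, a feedback inhibitor of cytokine signalling, was 28.1-fold higher (4.81 ± 0.18 on the log2 scale, SE, adjusted p = 2.45e-11). Slc17a8, a vesicular glutamate transporter, rose by 5.60 ± 0.35, from 2.89 ± 0.21 in WT (SD, n = 4) to 8.49 ± 1.19 in T2F3 (SD, n = 3). Ccn3, a secreted matricellular protein, rose by 4.68 ± 0.17. The other largest rises were Cd207, which encodes langerin (3.81), the actin regulator Enah (3.75), the integrin Itgae, which encodes CD103 (3.54), and the BCL2-family genes Bcl2a1a (3.96) and Bcl2a1d (3.78). The last pair are near-identical copies, so their split is uncertain. The largest falls were Greb1 (-3.45 ± 0.58, SE), the red cell gene Ermap (-3.31), carbonic anhydrase Car1 (-3.17) and Atp1b2 (-2.96). Next came the angiopoietin receptor Tek (-2.92), the membrane skeleton gene Add2 (-2.80), Prkg1 (-2.77) and the pyruvate kinase Pklr (-2.76). Greb1 varied widely within WT MPP, from 4.28 to 8.30, so the size of its fall is uncertain. In each of these 16 genes every T2F3 MPP library lay on one side of every WT MPP library, as the naming rule required.

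Erythroid genes fell almost as a whole in T2F3 MPP. Of 18 measured, 0 rose and 17 fell (0 and 17 adjusted over the list alone), with a median of -1.82, a camera adjusted p of 2.74e-12, and an adjusted p of 0.183 with an estimated correlation. The transcription factor Gata1 differed by -2.45 ± 0.17 (SE) and the membrane skeleton gene Ank1 by -2.53 ± 0.17. Klf1 (-2.19) and the erythropoietin receptor Epor (-1.98), chosen after their values were seen, were also lower. Of 15 B lymphoid genes, 1 rose and 10 fell (1 and 11 adjusted over the list alone), with a median of -1.28, a camera adjusted p of 6.44e-06, and an adjusted p of 0.289 with an estimated correlation. The B cell factor Ebf1 differed by -2.17 ± 0.19. Cd79a (-2.46), an antigen receptor partner, was picked after seeing the values. Of 19 early lymphoid genes, 2 rose and 10 fell (2 and 11 adjusted over the list alone), with a median of -0.36, a camera adjusted p of 0.00287, and an adjusted p of 0.269 with an estimated correlation. A member picked after seeing its value, the terminal transferase gene Dntt, did not pass (-0.06, adjusted p = 0.776).

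Among 21 dendritic cell genes, 14 rose and 0 fell in T2F3 MPP (14 and 1 adjusted over the list alone). The median was 1.83, with a camera adjusted p of 4.44e-08 and an adjusted p of 0.287 with an estimated correlation. Those that rose included the MHC class II genes H2-Aa (3.01 ± 0.23, SE) and H2-Ab1 (2.86). Examples taken after the values were seen were Xcr1 (2.74), Clec9a (2.44) and Batf3 (2.39), all known from conventional dendritic cells that cross-present antigen. Siglech, a plasmacytoid dendritic cell gene, stood at -0.51 ± 0.25 (SE, adjusted p = 0.106). Of 25 monocyte and macrophage genes, 20 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 1.36, a camera adjusted p of 1.05e-09, and an adjusted p of 0.183 with an estimated correlation. Lgals3 rose by 2.26. The chemokine receptor Ccr2 (2.20) and the myeloid factor Irf8 (1.58), further picks after seeing the values, were higher too.

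Signalling targets moved in different directions. Of 12 STAT5 and cytokine feedback targets, 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.60, a camera adjusted p of 1.13e-04, and an adjusted p of 0.205 with an estimated correlation. Cish, another feedback inhibitor, rose by 2.02 ± 0.16 (SE). In contrast, 7 of 10 MAPK feedback targets fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.61, a camera adjusted p of 0.00176, and an adjusted p of 0.183 with an estimated correlation. After the values were seen, the ERK phosphatase gene Dusp6 (-1.76) and Etv5 (-1.60) were picked from those that fell, and Dusp5 (1.26) is the one that rose. Of 18 NF-kB and inflammatory genes, 10 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.35, a camera adjusted p of 3.63e-04, and an adjusted p of 0.183 with an estimated correlation. Cd83, an activation marker, rose by 2.95 ± 0.23. Of 34 interferon response genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone), with a median of 0.62, a camera adjusted p of 2.09e-06, and an adjusted p of 0.425 with an estimated correlation. Mx1 (1.97) and Irf7 (1.64) were picked as examples after seeing the values.

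In the HOX and MEIS list, 11 of 12 genes fell in T2F3 MPP and 0 rose (11 and 0 adjusted over the list alone), with a median of -0.68, a camera adjusted p of 6.56e-06, and an adjusted p of 0.183 with an estimated correlation. Meis1 (-0.79) and Hoxa9 (-0.63), 2 such examples chosen after seeing the values, are homeobox factors of immature cells. The stem cell list was split, as 16 of 34 genes fell and 8 rose (18 and 8 adjusted over the list alone), and it missed the threshold with camera (adjusted p = 0.0587, and 0.563 with an estimated correlation). With fry it passed as lower (adjusted p = 0.0153). Tek fell, while the MYC-family gene Mycn (2.00 ± 0.15, SE) and Ifitm1 (2.70) rose. Of 20 cholesterol synthesis genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 0.80, a camera adjusted p of 3.08e-09, and an adjusted p of 0.183 with an estimated correlation. Idi1 (1.35) and Msmo1 (1.41), enzymes of that pathway chosen after seeing the values, were among them. The glycolytic aldolase Aldoc rose by 1.86 and the leukocyte gene Lsp1 by 1.60.

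Ribosomal protein genes were higher in T2F3 MPP, where 60 of 76 rose and 0 fell (71 and 0 adjusted over the list alone), with a median of 0.72 and an adjusted p of 0.425 with an estimated correlation. Of 46 oxidative phosphorylation genes, 28 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 0.55. Camera gave adjusted p = 6.99e-11 and 9.07e-07, and with an estimated correlation the oxidative phosphorylation list had an adjusted p of 0.425. Other genes spanning under 3 kb were higher as well, by 0.20 ± 0.02 on average (SE, 778 genes).

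**Figure D3:**
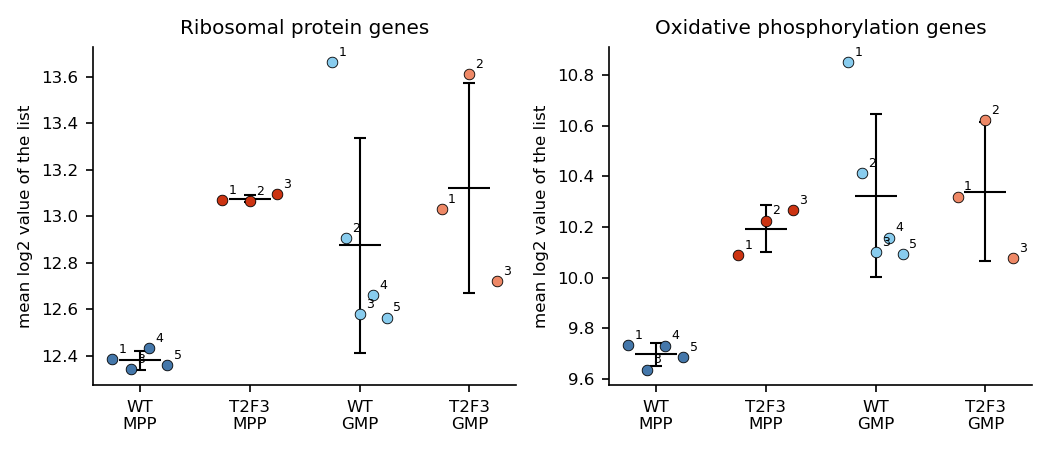
Mean log2 value (y axis) of the ribosomal protein genes (left, 76 genes) and the oxidative phosphorylation genes (right, 46 genes) in each library of the 4 groups (x axis), with replicate numbers at the points and bars for the group mean and SD. T2F3 MPP libraries lie above WT MPP libraries, and WT GMP 1 and T2F3 GMP 2 lie above the other GMP libraries.

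In all, 4889 of 12133 genes passed an adjusted p of 0.05 in MPP, 2506 higher and 2383 lower in T2F3, and 626 of them differed by over 2-fold (445 higher, 181 lower). Of the 30 lists tested, 16 passed with camera, and 0 did with an estimated correlation. The count of genes fell to 2859 without T2F3 MPP 2 and to 2892 without T2F3 MPP 3. With each library centred on its median, 40.2% of the called genes were higher, against 51.3%.

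The second comparison asked the same in granulocyte-macrophage progenitors. By camera, the dendritic cell, interferon response and monocyte lists were higher in T2F3 GMP, and the basophil and mast cell list and the erythroid list were lower. None of them passed with an estimated correlation, where the adjusted p was 0.153, 0.177, 0.153, 0.153 and 0.171 in that order. Socs2 was 10.3-fold higher (3.36 ± 0.17 on the log2 scale, SE, adjusted p = 3.50e-09). The MHC class II genes H2-Aa (3.28 ± 0.22), H2-Eb1 (3.18 ± 0.22) and Cd74, their invariant chain (3.01 ± 0.21), were next to the C-type lectin Cd209a (3.27), the cytoskeletal gene Septin3 (3.06), ceruloplasmin Cp (2.93) and the toll-like receptor Tlr11 (2.93) among the largest rises. The largest falls were the basophil protease Prss34 (-2.86 ± 0.32), Gdf3 (-2.50), Slc45a3 (-2.35), the IgE receptor subunits Fcer1a (-2.35) and Ms4a2 (-2.15), platelet factor Pf4 (-2.27), the mast cell protease Cpa3 (-2.11) and the transcription factor Gata2 (-2.08 ± 0.17). In these 16 genes the 3 T2F3 GMP libraries lay apart from the 5 WT GMP libraries, again as the naming rule required.

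Of 17 basophil, mast cell and eosinophil genes, 1 rose and 12 fell in T2F3 GMP (2 and 14 adjusted over the list alone), with a median of -1.16, a camera adjusted p of 2.05e-10, and an adjusted p of 0.153 with an estimated correlation. Gzmb (-2.07) and the eosinophil peroxidase Epx (-1.92) were chosen after their values were seen. Erythroid genes were lower here too, as 14 of 18 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -1.08, a camera adjusted p of 9.72e-12, and an adjusted p of 0.171 with an estimated correlation. Gata1 differed by -1.63 ± 0.16 (SE), and Klf1, chosen after seeing its value, by -1.33. Of 15 megakaryocyte genes, 1 rose and 7 fell (2 and 8 adjusted over the list alone), with a median of -0.76, a camera adjusted p of 0.00144, and an adjusted p of 0.229 with an estimated correlation. Of 15 B lymphoid genes, 1 rose and 8 fell (1 and 9 adjusted over the list alone), with a median of -0.71, a camera adjusted p of 0.00109, and an adjusted p of 0.377 with an estimated correlation.

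Dendritic cell genes rose in T2F3 GMP, 16 of 21, and 1 fell (17 and 1 adjusted over the list alone), with a median of 1.60, a camera adjusted p of 1.85e-19, and an adjusted p of 0.153 with an estimated correlation. Flt3 is a member. Chosen after their values were seen, the class II transactivator Ciita (2.78), Xcr1 (2.78) and Clec9a (2.72) were also higher. Of 34 interferon response genes, 23 rose and 0 fell (28 and 0 adjusted over the list alone), with a median of 0.70, a camera adjusted p of 3.40e-14, and an adjusted p of 0.177 with an estimated correlation. Mx1 (2.01) and Irf7 (1.83) were again picked after seeing the values. Of 25 monocyte and macrophage genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.94, a camera adjusted p of 3.24e-12, and an adjusted p of 0.153 with an estimated correlation. Ctss, a lysosomal protease, rose by 1.65 ± 0.17 (SE). Ccr2 (1.28) and Irf8 (0.94) were picks made after seeing the values.

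The NF-kB and inflammatory list had 18 members, of which 6 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 0.34, a camera adjusted p of 3.29e-06, and an adjusted p of 0.153 with an estimated correlation. Cd83 rose by 2.52 ± 0.22 (SE) and the signalling adaptor Traf1 by 1.65 ± 0.14. Of 12 STAT5 and cytokine feedback targets, 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.27, a camera adjusted p of 0.00306, and an adjusted p of 0.311 with an estimated correlation. Cish rose by 1.73. Among 10 MAPK feedback targets, 6 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.46, a camera adjusted p of 0.00893, and an adjusted p of 0.225 with an estimated correlation. Dusp6, chosen after seeing its value, differed by -1.39. Aldoc (1.65), Lsp1 (1.73) and Ifitm1 (1.84) rose in GMP as well. Neutrophil primary granule genes showed 0 rises and 1 fall among 20 (0 and 1 adjusted over the list alone, camera adjusted p = 0.211), and the myeloperoxidase gene Mpo stood at -0.51 ± 0.22 (SE, adjusted p = 0.124, chosen after seeing its value). Of 20 late neutrophil genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.87, a camera adjusted p of 1.08e-04, and an adjusted p of 0.377 with an estimated correlation. The list varied widely within WT GMP, where its median deviation from the other libraries of the group ran from -0.93 (WT GMP 3) to 0.74 (WT GMP 4).

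In GMP, 1855 of 12133 genes passed, 1122 higher and 733 lower in T2F3, and 420 differed by over 2-fold (339 higher, 81 lower). Of the 30 lists, 16 passed with camera and 0 with an estimated correlation. The ribosomal protein list was among the 16, with a median of 0.27, although 0 rose and 1 fell of 76 (0 and 0 adjusted over the list alone). Its camera adjusted p was 0.00273, and its adjusted p 0.795 with an estimated correlation. The gene count was 3759 without WT GMP 1 and 1174 without T2F3 GMP 2, the 2 libraries with raised ribosomal protein genes. It was 4267 with the ribosomal protein score as a covariate, an alternative chosen after the data were seen.

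**Figure D4:**
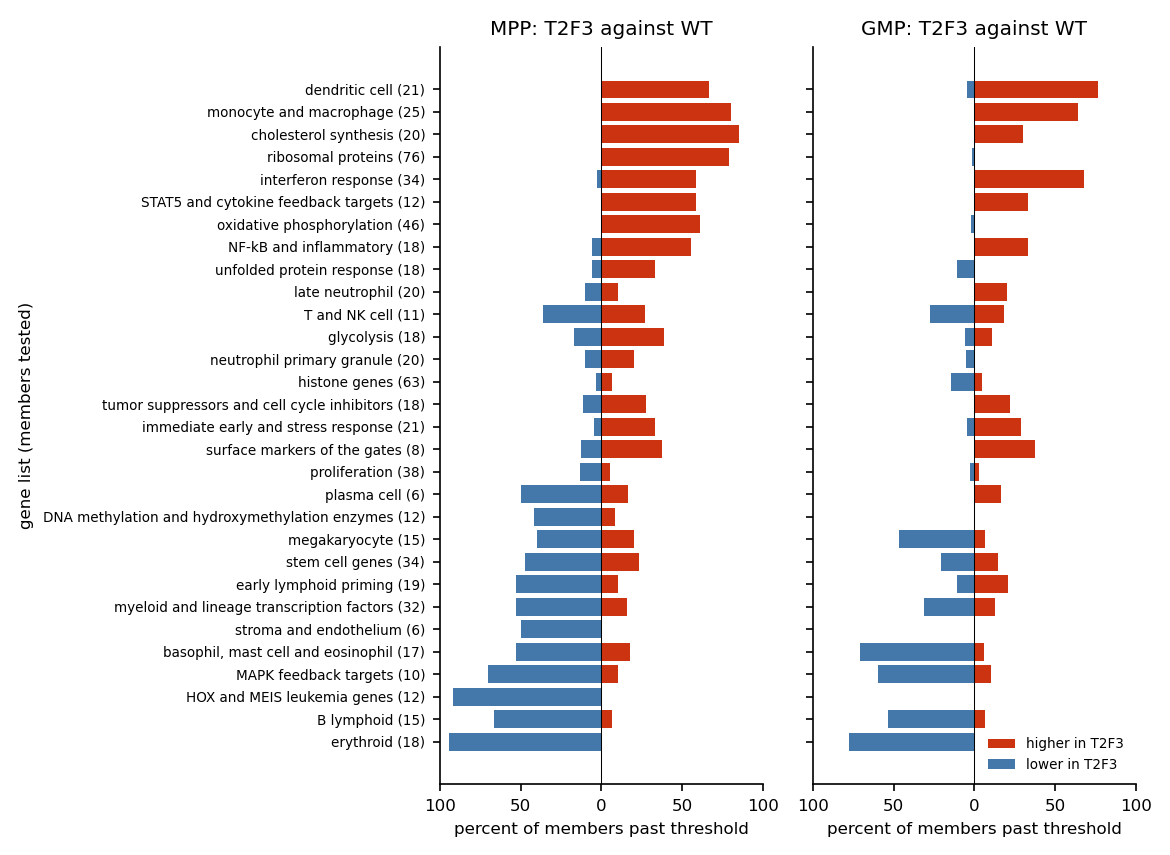
Percent of tested members of 30 gene lists (y axis, with the number of members) that passed the threshold, with those higher in T2F3 to the right and those lower to the left, in MPP and GMP. Dendritic cell, monocyte and interferon genes lie to the right in both populations and erythroid genes to the left, while ribosomal protein genes lie to the right in MPP (60 of 76).

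The genotype effects in the 2 populations were then set side by side. Of the 1275 genes called in both, 809 were higher in T2F3 in both, 451 were lower in both and 15 went opposite ways. Independent calls would give 232, 144 and 372. The 1260 genes called in one direction became 2556 (1433 higher, 1123 lower) without WT GMP 1 and 3067 with the ribosomal protein score as a covariate. Across genes, which are not independent replicates, the log2 differences had r = 0.763 and rho = 0.646. When the T2F3 genotype was assigned to other sets of 3 replicate numbers with the same group sizes, the median r was 0.405 and the highest 0.781. The MPP and GMP libraries are different libraries, although equal numbers may mark the same animal.

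The interaction tested whether the genotype effect differed between the populations. Slc17a8 and Mycn rose in T2F3 MPP, and the difference of their genotype effects, GMP minus MPP, was -5.07 ± 0.48 and -2.33 ± 0.21 (SE), with limma adjusted p = 4.43e-05 for both. The genotype effect was also lower in GMP for the metalloproteinase inhibitor Timp3 (-2.59), Enah (-2.22), the kinase subunit Camk2b (-2.08), Ccn3 (-1.98), the basophil protease Mcpt8 (-1.89), Gzmb (-1.55), Socs2 (-1.45) and the T cell genes Lck (-1.32) and Lat (-1.30). It was higher in GMP for the syndecan gene Sdc1 (2.04), Slc16a11 (1.91), the integrin Itga9 (1.89), Tek (1.87 ± 0.15), the lipoprotein receptor Vldlr (1.76), Prkg1 (1.67), the chromatin organizer Satb1 (1.21) and Ank1 (1.20). A positive value need not be a rise in GMP. Tek lay at 6.3 to 6.5 in WT MPP, 4.4 to 4.6 in WT GMP and 3.4 to 3.5 in the T2F3 libraries of both populations. For cholesterol synthesis genes the effect was lower in GMP, with 2 of 20 members past the threshold (10 adjusted over the list alone) and a median of -0.48. Camera gave an adjusted p of 2.69e-08, and the adjusted p was 0.293 with an estimated correlation. For HOX and MEIS genes it was higher in GMP, with 1 of 12 members (9 adjusted over the list alone), a median of 0.60, a camera adjusted p of 5.23e-07, and an adjusted p of 0.204 with an estimated correlation. For erythroid genes it was higher in GMP by a median of 0.80, with 4 of 18 members (9 adjusted over the list alone), a camera adjusted p of 2.75e-07, and an adjusted p of 0.376 with an estimated correlation. The erythroid list was lower in T2F3 in both populations, with medians of -1.82 in MPP and -1.08 in GMP, so its positive value is a smaller fall in GMP. The HOX and MEIS medians were -0.68 in MPP and -0.11 in GMP. In all 274 genes passed, 167 positive and 107 negative. That count was 1204 (399 positive, 805 negative) without WT GMP 1 and T2F3 GMP 2, and it ran from 79 without T2F3 MPP 3 to 586 without T2F3 MPP 1. With each library centred on its median, 74.5% of the called genes were positive, against 60.9%.

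**Figure D5:**
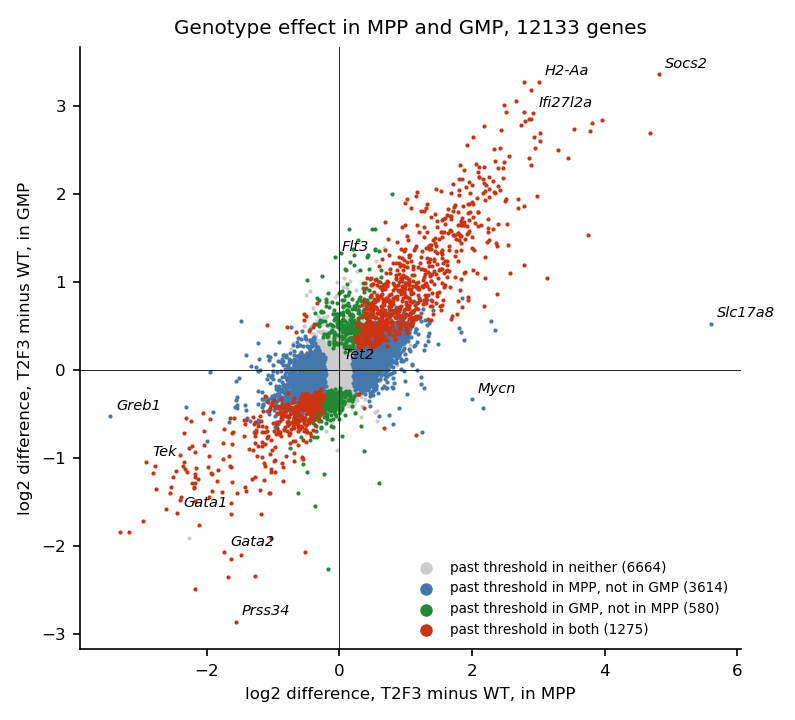
Log2 difference between T2F3 and WT in MPP (x axis) and in GMP (y axis) for 12133 genes, where each point is a gene and color shows in which population it passed an adjusted p of 0.05. Most of the 1275 genes past the threshold in both lie in the same direction. Slc17a8 lies far out on the MPP axis (5.60), and Mycn less far (2.00).

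The last comparisons set GMP against MPP within each genotype. In WT marrow, the largest rises from MPP to GMP included the eosinophil genes Prg2 (3.36 ± 0.35, SE) and Epx (3.16 ± 0.22), the cathelicidin Camp (3.06), S100a9 (2.81), S100a8 (2.78), Prss34 (2.74), Prg3 (2.70) and Wfdc21 (2.67). The largest falls included Dntt (-4.18 ± 0.14, SE), Vldlr (-3.79), the immunoglobulin joining chain Jchain (-3.45), Robo4 (-3.19), Sgsm1 (-3.10), Mn1 (-3.05) and the homeobox gene Nkx2-3 (-2.92). Flt3 fell by 2.57 on the log2 scale (SE 0.11). Of 34 stem cell genes, 1 rose and 33 fell (1 and 33 adjusted over the list alone), with a median of -1.54, a camera adjusted p of 8.33e-19, and an adjusted p of 0.0532 with an estimated correlation. Of 20 primary granule genes, 19 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 1.80, a camera adjusted p of 1.87e-12, and an adjusted p of 0.0532 with an estimated correlation. The neutrophil elastase gene Elane rose by 2.27 ± 0.14. Fcgr3, which encodes the CD16 used to sort GMP, differed by 2.11 and was chosen after seeing its value. In all, 5899 genes passed (3081 higher, 2818 lower in GMP), 1102 by over 2-fold, and 22 lists passed with camera against 0 with an estimated correlation. With each library centred on its median, 42.2% of the called genes were higher, against 52.2%.

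In T2F3 marrow, the largest rises from MPP to GMP were S100a9 (3.52 ± 0.56, SE), S100a8 (3.47), Camp (3.45), Ngp (3.43), the closely related pair Chil3 (3.30) and Chil4 (3.28), whose split is uncertain, Itgb2l (3.24) and lactoferrin Ltf (3.23). The falls were led by Slc17a8 (-5.23 ± 0.37), Mycn (-4.44 ± 0.17), Dntt (-4.35 ± 0.17), Gimap3 (-3.50), Ctla2a (-3.25), Gimap6 (-3.12), Myl10 (-3.12) and Lck (-3.07). Flt3 fell by 1.23 on the log2 scale (SE 0.13). Of 34 stem cell genes, 0 rose and 28 fell (0 and 30 adjusted over the list alone), with a median of -1.27, and of 20 primary granule genes, 19 rose and 0 fell (19 and 0 adjusted over the list alone), with a median of 1.16. Camera gave adjusted p = 1.28e-22 and 7.08e-16, and with an estimated correlation the adjusted p was 0.0332 for both. Of 20 late neutrophil genes, 18 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 2.16, a camera adjusted p of 5.11e-14, and an adjusted p of 0.196 with an estimated correlation. In all, 2690 genes passed (1272 higher, 1418 lower in GMP), 731 by over 2-fold, and 18 lists passed with camera against 2 with an estimated correlation. The count was 4209 with the ribosomal protein score as a covariate.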

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

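Tests in this part were chosen after the result they bear on was seen, except the prediction of the ribosomal shift in MPP and the splits for the gene lists and for the GMP count with the ribosomal protein score, of which those for the difference of effects were later restricted as stated below.

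WT GMP 1 and T2F3 GMP 2 deviated from their groups in the same genes (r = 0.809 across genes, which are not independent), with ribosomal protein genes raised by 1.08 and 0.81. Better recovery of short transcripts may contribute. Genes spanning under 3 kb exceeded longer genes by 0.278 and 0.242 in these libraries, against -0.231 to 0.0588 in the other 6 GMP libraries. The -0.231 is T2F3 GMP 3, which deviated nearly as far the other way. The values of 0.278 and 0.242 lie between the bounds of 0.3 and 0.1 set for the test, and span is not transcript length. For mature neutrophils the mean deviation of late neutrophil genes minus that of ribosomal protein genes was -0.526 (SE 0.187) in WT GMP 1 and -0.261 (SE 0.203) in T2F3 GMP 2. The latter lies within 2 SE, so mature neutrophils stay open as well. The lineage-negative and c-Kit-positive gate is meant to remove them, but the late neutrophil gene S100a8 was read at 13.7 to 17.2 over the GMP libraries. It was the highest of its group in WT GMP 1 and T2F3 GMP 2, while Ltf and Ngp, of the same list, were not. A first reading of this test, on medians (0.314 and 0.335 for late neutrophil genes against 1.08 and 0.812), had counted against neutrophils before means were used with their SE. The labels give no group that sets these libraries apart, so no biological difference named by the design was tested.

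Ribosomal protein genes were higher in T2F3 MPP by 0.696 (SE 0.0221, mean over 76 genes). Within the GMP groups, the ribosomal mean moved by 3.16 (SE 0.108) per unit of the mean of other short genes. That slope and the short-gene difference of 0.199 (SE 0.0185) predict 0.628 (SE 0.0622), which is 90.2% (SE 9.39) of the observed shift. Without WT GMP 1 and T2F3 GMP 2, a check added after this result, the slope was 2.68 (SE 0.104) over 6 libraries. It predicted 76.5%, just under the 80% that the test asked for. Both predictions need the GMP slope to hold in MPP, which was not tested. Against the rest of their group, short genes of the MPP libraries ran from -0.064 (WT MPP 3) to 0.035 (WT MPP 5) in the median. Ribosomal protein genes stood at -0.054 and -0.029 in these 2, which does not follow that slope. Better recovery of short transcripts in the T2F3 MPP libraries therefore stays open. An effect of the genotype on these genes would move with the same libraries, so it stays open and untested.

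Flt3 and dendritic cell genes were higher in T2F3 GMP, and MPP cells inside that gate could raise Flt3 to its level at a share of 30.5%. The dendritic cell genes H2-Aa, H2-Ab1, H2-Eb1, Clec9a, Ciita and Cd74 would need 51.1% to 56.9%, so the share for Flt3 would not bring them to their level. The needed share below is the one for Flt3. Of 3 gene sets tried in turn, the first gave only upper limits, the lowest 30.9% (Ifitm1), and the second held genes of the pattern itself, so neither decides, while the third, 13 genes at least 4-fold higher in both MPP groups than in WT GMP, implied a median of 3.94% (12 of 13 under the needed share), and 5.50% without Dntt and Ctla2a, which were known to be low when it was chosen. That argues against such cells, but with a minimum of 2-fold, added later, the medians were 18.2% to 23.5% over 57 to 208 genes, above the bound of 50% of the needed share that was set before these were run, so MPP cells are not excluded. One kind of dendritic cell in both T2F3 gates could also raise these genes, and the profiles of added transcripts gave an F test p of 0.419, in a test that replaced a chi-square test after its result was seen and that ran on the 13 dendritic cell genes picked because they rose in both gates, so it shows neither one cell kind nor equal profiles. Genes raised inside the progenitors are a further possibility, Flt3 passed in GMP and not in MPP, the lineage-negative and c-Kit-positive gates are meant to remove mature dendritic cells, and the genotype stays open.

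The genotype effect was tested for a difference between populations, and 274 genes passed. Among named genes it was lower in GMP for Slc17a8 (-5.07), Timp3 (-2.59), Mycn (-2.33), Enah (-2.22), Camk2b (-2.08), Ccn3 (-1.98), Mcpt8 (-1.89), Gzmb (-1.55), Socs2 (-1.45), Lck (-1.32), Lat (-1.30), Id1 (-1.11), Mvd (-1.001), Ifitm1 (-0.86), Gadd45b (-0.84) and Itgae (-0.80). It was higher in GMP for Sdc1 (2.04), Slc16a11 (1.91), Itga9 (1.89), Tek (1.87), Vldlr (1.76), Prkg1 (1.67), Add2 (1.62), Ermap (1.46), Pklr (1.40), Flt3 (1.34), Atp1b2 (1.24), Satb1 (1.21), Ank1 (1.20), Hlf (1.11), Ebf1 (1.05) and Meis1 (0.67). Hlf and Meis1 were chosen after their values were seen. A positive value can be a smaller fall in GMP, as for the erythroid list, whose medians were -1.82 in MPP and -1.08 in GMP. With camera, 16 lists passed, and 0 did with an estimated correlation. Their medians, GMP minus MPP, were 0.80 for erythroid, 0.71 for stroma and endothelium, 0.69 for B lymphoid, 0.66 for late neutrophil, 0.60 for HOX and MEIS, 0.50 for early lymphoid and 0.14 for stem cell genes. They were -0.63 for basophil and mast cell, -0.49 for unfolded protein response, -0.48 for oxidative phosphorylation and for cholesterol synthesis, -0.45 for ribosomal protein, -0.34 for STAT5, -0.23 for monocyte, -0.22 for primary granule and -0.16 for histone genes.

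Single libraries lay far from the rest of their group in 17 of 250 checks of named genes and list means, where chance gives about 1 in 20, or 12.5. In WT MPP 1, Cd74 (11.01), H2-Aa (10.03) and H2-Eb1 (9.40) were low and Hlf (11.05) and Meis1 (10.43) high against the other 3 WT MPP libraries. Elsewhere in WT MPP the values were Cd207 at 3.53 and Ermap at 7.35 in library 5, Emcn at 5.20 and Mpo at 15.69 in library 3, and Wfdc21 at 7.02 in library 4. In WT GMP they were Lck at 5.96 and Slc17a8 at 2.87 in library 1, Atp1b2 at 6.72 and Klf1 at 6.44 in library 2, Lgals3 at 8.26 and Prkg1 at 4.44 in library 3, and Ccr2 at 10.05 in library 4.

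Other splits of the same libraries were refitted. For MPP, 1 of 35 splits reached the real count of 4889 genes (highest other 570), a share under 0.05 and the lowest that 35 splits can give. For GMP, 3 of 56 did (real 1855, highest other 4120, for T2F3 GMP 1, T2F3 GMP 2 and WT GMP 1 together), so chance cannot be excluded, and that split puts the 2 libraries with raised ribosomal protein genes on one side, which points to a structure of the samples. With the ribosomal protein score 2 of 56 did (real 4267, highest other 4684), a share under 0.05. The same split still gave more genes than the real one, and the covariate was chosen after the data were seen, so this count does not exclude chance. The real count was also the largest for the difference of effects (1 of 35, real 274, highest other 0). The same held for the genes called in both populations in one direction (1 of 35, real 1260, highest other 0). These splits reassigned the genotype in both populations at once, so they test for no genotype effect at all. They cannot exclude chance for a difference between the effects. For the WT step the real count was the largest too (1 of 100 drawn, real 5899, highest other 4017), a share under 0.05. Chance cannot be excluded for the correlation of the effects (4 of 35, real 0.763, highest other 0.781). The 10 splits of the T2F3 step are too few for a share under 0.05 (1 as large, real 2690, highest other 0). For the number of gene lists chance cannot be excluded in MPP (7 of 35, real 16, highest other 19), GMP (6 of 56, real 16, highest other 20) and the WT step (8 of 100, real 22, highest other 24). For the difference of effects the real count was the largest (1 of 35, real 16, highest other 14), a share under 0.05. Other assignments gave nearly as many lists, and 0 passed with an estimated correlation, so that margin does not exclude chance. In the T2F3 step the splits are too few (2 of 10, real 18, highest other 19). For the difference of effects, the genes called in both and the correlation, the splits reassigned replicate numbers over both populations, and WT 2 has no MPP library, so only 35 of the 56 assignments keep the group sizes. All 56 were counted first, and the restriction to 35 was made after those results were seen. Over all 56, the highest others were 10 genes and 15 lists for the difference of effects, 0 for the genes called in both and 0.795 for the correlation (6 as large). The real counts of genes were thus the largest over all 56 as well, while 15 lists against the real 16 leave chance open for the lists.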

How the results depend on the processing

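The alternatives here that were chosen after seeing the data are leaving out WT GMP 1 and T2F3 GMP 2, the ribosomal protein score as a covariate, and a sex term. The cause of each change below was not tested, except where fewer genes or libraries or a stricter null make it plain.

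For the difference of effects, 274 genes became 436 with no filter, 140 at a minimum mean of 6, 1494 with array weights, 16 against a log2 difference of 0.5, 1204 without WT GMP 1 and T2F3 GMP 2 and 2452 with the ribosomal protein score. For MPP, 4889 became 7795 with array weights and 546 against a difference of 0.5. For GMP, 1855 became 4103 with array weights, 1180 with only its groups fitted, 337 against 0.5 and 4267 with the ribosomal protein score. The WT step gave 1320 against 0.5. The T2F3 step gave 4389 with array weights, 660 against 0.5 and 4209 with the ribosomal protein score. Genes called in both populations in one direction were 3336, 267 and 3067 under these 3 settings. Lists past the threshold with an estimated correlation were 0 for MPP, 0 for GMP, 0 for the difference, 0 for the WT step and 2 for the T2F3 step, and with fry, which tests each list on its own, 22, 17, 6, 26 and 21. The Tet2 difference changed sign, at -0.11 in GMP and -0.086 for the difference of effects with array weights and at -0.020 in GMP without WT GMP 1 and T2F3 GMP 2. In the T2F3 step the ribosomal protein list (adjusted p = 0.689) changed sign under quantile normalization (adjusted p = 0.00318) and without those libraries (adjusted p = 7.82e-05).

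With 1 library left out, counts ran from 2859 (T2F3 MPP 2) to 5989 in MPP, 1174 (T2F3 GMP 2) to 3759 (WT GMP 1) in GMP, 79 (T2F3 MPP 3) to 586 (T2F3 MPP 1) for the difference, 5115 to 6255 in the WT step, 2077 to 3176 in the T2F3 step and 907 to 2556 (WT GMP 1) for genes called in both. MPP gave 2892 without T2F3 MPP 3. The difference gave 107 without T2F3 GMP 3, 117 without WT MPP 3, 121 without WT MPP 4, 133 without T2F3 MPP 2, 137 without WT MPP 1, 180 without T2F3 GMP 2, 181 without WT GMP 2 and 182 without WT GMP 5. Lists ran from 16 to 18, 16 to 19, 11 to 18, 22 to 22 and 17 to 22. Tet2 in GMP ran from -0.037 (T2F3 GMP 2, where its sign changed) to 0.17, and the adjusted p of the ribosomal protein list in the T2F3 step from 0.00868 (T2F3 GMP 3) to 0.774, with its sign changed at 0.0371 (T2F3 GMP 2).

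The numbers do not show pairing by the bound used: same-numbered MPP and GMP libraries of a genotype had correlations of deviations of 0.055 to 0.464, not all over 0.1, and 4 of 7 MPP libraries correlated best with their own number. The sex read from Ddx3y matched in 7 of 7 such pairs, of which 2 were male, as in a share of 0.0667 of all renumberings within genotypes, so shared animals stay possible. With genotype and number as 1 animal in the block, 4854 genes passed in MPP, 1867 in GMP and 400 for the difference. With the number alone as a block, which ties WT to T2F3 libraries that nothing else links, 2732, 1302 and 242 passed. For single genes and lists, 3969 values under the other alternatives kept their side of the threshold, 153 were no longer past it, 49 newly passed it and 5 changed sign. The 153 include the camera list calls lost with an estimated correlation. With 1 library left out, the numbers were 4966, 45, 42 and 2. In both sets a list that changed direction while past the threshold in neither fit counts as kept, so sign changes of such lists are not counted. The depth of the libraries is unknown, so no limit from depth is given.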

Other observations

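The test of the last paragraph was chosen after its result was seen, and the genes named here outside the naming rule were chosen after their values were seen. Enzymes of DNA methylation and its oxidation showed 1 rise and 5 falls among 12 genes in T2F3 MPP (1 and 5 adjusted over the list alone) and missed the threshold as a list with camera (adjusted p = 0.158, and 0.425 with an estimated correlation). With fry, which tests each list on its own, the list passed as lower (adjusted p = 0.012). The Tet2 relatives Tet1 (-0.70 ± 0.14, SE) and Tet3 (-0.46 ± 0.13) were among the falls (adjusted p = 0.00109 and 0.0115). In GMP 0 rose and 0 fell with limma, and 5 of 12 had an unadjusted p under 0.05 (0 and 0 adjusted over the list alone, camera adjusted p = 0.154). There too the list passed as lower with fry (adjusted p = 0.0388). The surface marker list held genes of the sorting gates and others that are not in those gates, such as Flt3. Among its 8 tested genes, 3 rose and 1 fell in MPP (3 and 1 adjusted over the list alone, camera adjusted p = 0.342, adjusted p = 0.425 with an estimated correlation, fry adjusted p = 0.00404). Kit, which encodes the c-Kit receptor of both gates, was lower in T2F3 MPP (-0.92 ± 0.14, adjusted p = 1.63e-04), and Cd48 was higher (1.53 ± 0.17, adjusted p = 6.70e-06). In GMP Kit stood at -0.23 ± 0.14 (adjusted p = 0.282).

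From MPP to GMP in WT, 16 of 18 unfolded protein response genes rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 0.88, a camera adjusted p of 1.53e-07, and an adjusted p of 0.184 with an estimated correlation. Of 11 T and NK cell genes, 0 rose and 10 fell (0 and 10 adjusted over the list alone), with a median of -1.05, a camera adjusted p of 2.97e-06, and an adjusted p of 0.0798 with an estimated correlation. Interferon response genes were lower in WT GMP than in WT MPP, as 22 of 34 fell and 0 rose (22 and 0 adjusted over the list alone), with a median of -0.80, a camera adjusted p of 1.34e-07, and an adjusted p of 0.275 with an estimated correlation. Of 38 proliferation genes, 21 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 0.30, a camera adjusted p of 7.34e-05, and an adjusted p of 0.275 with an estimated correlation. In GMP, 4 of 18 tumor suppressors and cell cycle inhibitors rose in T2F3 and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.15, a camera adjusted p of 0.00893, and an adjusted p of 0.171 with an estimated correlation.

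A hypothesis from these values is that the genotype may narrow the difference between the populations. The slope of the T2F3 step on the WT step across genes, corrected for error, was 0.738, and 0.749 without WT GMP 1 and T2F3 GMP 2. A slope under 1 can also come from steps of equal size that involve partly different genes. The SD of the step across genes, likewise corrected, was 0.582 in WT and 0.478 in T2F3. Of 56 ways to assign 3 replicate numbers to one genotype, 2 gave a slope as low, the real one included, and the lowest other was 0.730 (T2F3 2, T2F3 3 and WT 2), with a median of 1.10. WT 2 has no MPP library, and among the 35 ways that keep the group sizes the real slope was the lowest (lowest other 0.827, median 1.11). That count was added after the first was seen, and the bound set for the test asked for the lowest slope of all 56, so it is left open.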
